A study of Mus musculus with 2 samples.

How the data were processed

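Gene expression was measured in mouse epiblast stem cells (EpiSC), pluripotent cells that correspond to the epiblast of the embryo after implantation. Per the labels, 2 clones were profiled at passage 9, both wildtype, female and of C57BL/6 background, with 1 array each. Cells were collected with trypsin, total RNA was isolated with Trizol and a column, and Cy3-labelled cRNA was made from 0.2 ug of RNA, per the labels' protocols. No other cell type was among the samples. Each array was a 1-colour Agilent whole mouse genome array (design 026655) that was read with Feature Extraction 11.0.1.1 under protocol GE1_1100_Jul11, per the file headers. Both arrays came from the same slide and scan, so no slide or scan separates the clones.

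The values used are the processed signal intensity of each spot, which Feature Extraction had corrected for background and for spatial trends before the scanner files were deposited, per the file headers. These intensities were not normalized between arrays. Probe positions are on mm9 (NCBI37), per the file headers. The authors' deposited table of normalized values is also an intensity on a linear scale, and the method that made it is not given in the sources used here. Set against the scanner files probe by probe, its log2 values had Pearson correlations of 0.999 and 1.00 across probes with the processed signals of clone 1 and clone 2. Its differences between clones correlated at 0.993 with those after quantile normalization of the processed signals. The medians of its columns were 65.8 for clone 1 and 65.9 for clone 2. Of its 39429 entries, 52 carry 9 repeated probe identifiers and were left out, which left 39377. The table was used only as an alternative.

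Of 44397 spots per array, 43020 were not controls. Outlier flags removed 277 spots on the array of clone 1 and 246 on that of clone 2. Log2 processed signals were averaged over the spots of a probe, and the 75th percentile of all probes was subtracted on each array (a signal of 819 for clone 1 and 726 for clone 2). A probe counted as detected when at least 50% of its spots were well above background by the software's flag. In all, 157 probes whose every spot was flagged on an array were left out, among them the only probe of Col1a1. The median of 153 negative control spots was 7.96 for clone 1 and 7.13 for clone 2. The 75th percentile signal was 103 times and 102 times that median. Saturated spots numbered 0 and 1.

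Probes were named through a table of RefSeq genes of assembly GRCm38.p6, which was used for names only. Of 39429 probes, 26055 matched by accession, 3195 by symbol and 930 by an older symbol, and 9249 had no RefSeq gene and entered no gene count. The 22753 genes included 6042 with 2 or more probes. The value of a gene is that of its probe with the highest mean signal, and a gene is not detected only when none of its probes is. Where another probe changes the reading of a difference between clones, this is stated beside the gene.

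The direction is clone 2 minus clone 1 on the log2 scale throughout. With 1 array per clone there is no residual degree of freedom, so no p-value or standard error between clones was computed. Genes were counted when at least 2-fold apart, well above background on both arrays and not saturated on both. For a gene detected on 1 array only, the fold is a lower bound, taken as the bright value against the higher of the dim probe's own value and the lowest normalized signal among detected probes of the dim array (-4.54 and -4.55 on the log2 scale for clone 1 and clone 2). In total, 32 gene lists with 446 members, 441 of them measured, were fixed before the data were examined. The lists cover pluripotency states, germ layers and other cell types, signalling, imprinting, stress responses and metabolism. The number of members detected on both arrays was set against 10000 random gene lists of the same size. The median difference of members measured on both arrays (3 or more) was set against 10000 random lists matched on signal in 20 bins. Medians of chromosomes were treated in the same way. These percentiles describe the 2 arrays and are not tests between clones.

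Genes are named by a rule fixed at the same time. It covers 32 marker genes, list members at least 2-fold apart, the 12 genes with the largest difference per direction, and the 5 with the largest bound per direction, leaving out provisional names such as those of Rik clones. List members with a bound of at least 2-fold are named too. A gene that the rule takes by its bound is not reported here. Other list members serve as examples of their list, and further genes are marked as chosen after their values were seen.

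The noise between spots was taken from probes printed 10 times on an array. Over 260 such detected probes the median SD was 0.07 log2 for clone 1, and over 264 probes it was 0.08 for clone 2. For dim probes, with a signal below -2, the median SD was 0.11 for clone 1 and 0.13 for clone 2. At the medians over all these probes, a difference between single spots of the arrays has an SD of 0.11, or a 95% half-width of 0.21 (1.16-fold). This covers spot noise within arrays only, and not RNA preparation, labelling or culture. The number of arrays limits the precision.

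The steps were tested on simulated data with a noise SD of 0.1 log2, for the comparison of clone 2 with clone 1, with 13929 genes of which 200 were changed. The 2-fold count called 0% of genes changed 1.5-fold, 96% of those changed 2.5-fold and 100% of those changed 4-fold or 8-fold. Of 200 simulated lists of 12 unchanged genes, 9 lay outside the middle 95% of random lists. The simulated noise was independent between probes, so this does not show how often lists of genes that vary together would lie outside. Neither differences shared by neighbouring spots nor larger noise of dim probes were simulated. The rates of 2-fold calls therefore need not hold for the real arrays.

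Alternatives fixed at the same stage as the lists were quantile normalization, scaling to the median, normexp background correction of the raw spot and background intensities with an offset of 50, the authors' deposited values, the mean of all probes of a gene, other detection flags, no filter on dim probes, no saturated spots, and thresholds of 1.5-fold and 3-fold. Alternatives chosen after seeing the data left out spots with a 2-fold neighbour among their 6 nearest spots, removed the trend with the GC content of the probe in 20 bins, or left out probes placed on another chromosome than their gene or over 10 Mb from it. Of 29934 probes with a gene and a position, 120 were so placed, and 83 genes took their value from them, among them 1 list member, Gcm1. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.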

Results

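Expression profiles of EpiSC clone 1 and clone 2 were compared with 1 array each. The arrays were made to relate these lines to EpiSC described earlier, so the question is first which markers of pluripotency and of other cell types were present, and then how far the clones differed. Signals are log2 processed intensities relative to the 75th percentile of the array. Differences between clones have no replicate check.

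The clones had closely similar profiles. Of 22753 genes, 14476 were detected in clone 1 and 14534 in clone 2, and 13947 (61.3%) in both. A further 529 were detected in clone 1 only and 587 in clone 2 only, and 7690 in neither. Across 13928 genes measured on both arrays, Pearson's r was 0.990 and Spearman's rho 0.989 (across genes, which are not independent replicates). The SD of the differences between clones was 0.40 log2, and 90.9% of genes lay within 1.5-fold.

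Genes of the shared pluripotency network were detected in both clones. Of 20 core pluripotency genes, 18 were detected on both arrays, more than in most random lists (percentile 99.7, with a median of 12 in random lists). With the positive and significant flag, which calls more genes, the count was 19, inside the random range of 12 to 19 (percentile 96.0). Pou5f1 (Oct4), a transcription factor required for pluripotency, had a signal of 2.87 in clone 1 and 2.51 in clone 2, read by a probe on chromosome 17 from 35647280 to 35647340 in mm9. Nanog had 4.43 and 4.28, and its partner factor Sox2 had 0.16 and 0.45. Utf1, Lin28a and Sall4 were detected in both. Dppa2 was detected in neither clone. Dppa4 was detected in clone 2 only, but its brightest probe differed by just 0.38 log2 (-4.44 in clone 1 and -4.06 in clone 2). None of the 18 differed by 2-fold.

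Markers of the primed state of the postimplantation epiblast were present in both clones, 19 of 20 of them (percentile 99.96). With the positive and significant flag all 20 were detected on both arrays, above the random range of 12 to 19 (percentile 99.5). Against the negative controls the count was 19, inside the random range of 12 to 19 (percentile 96.98). Fgf5, a growth factor of the postimplantation epiblast, had 2.34 in clone 1 and 2.14 in clone 2. The transcription factors Otx2 (3.89 and 4.33) and Pou3f1 (4.10 and 4.12) and the de novo DNA methyltransferase Dnmt3b (5.98 and 6.23) were likewise measured in both. So were Nodal (2.75 and 3.04) and its feedback antagonists Lefty1 (4.12 and 4.25) and Lefty2 (-0.32 and -0.25). Cer1, another Nodal antagonist, was the member that was not well above background on either array. Cldn6, a tight junction protein, was 2.12-fold higher in clone 2.

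Naive markers, which are typical of embryonic stem cells and the preimplantation epiblast, were split. Of 20 such genes, 13 were detected on both arrays, close to the 12 of a random list (percentile 62.5). Zfp42 (Rex1), Nr0b1, Prdm14, Dppa3 (Stella), Tcl1, Nr5a2 and Piwil2 were not well above background in either clone. The naive factors Klf4 (-0.22 in clone 1 and -0.02 in clone 2), Klf2 (-2.26 and -1.83), Esrrb (-0.40 and -0.52), Tbx3 (-0.90 and -0.35) and Tfcp2l1 (-3.60 and -2.86) were detected in both. No naive gene differed by 2-fold.

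Of the lists for other lineages and stages, definitive endoderm and germ cell markers were detected on both arrays less often than the middle 95% of random lists, and for definitive endoderm this depended on the detection rule. For the primitive streak, 6 of 15 markers were detected on both arrays (percentile 5.25). Eomes was among them (-2.35 in clone 1 and -2.38 in clone 2). The streak and mesendoderm factors T (Brachyury), Foxa2, Mixl1 and Gsc were not. Wnt8a was detected in clone 2 only and was at least 3.04-fold higher there. Definitive endoderm had 2 of 10 markers on both arrays (percentile 0.635), without Sox17. Extraembryonic endoderm had 5 of 12 (percentile 9.02), and Gata6 was detected in clone 2 only, at least 1.32-fold higher. Trophoblast had 4 of 12 (percentile 3.08), without Cdx2, or 3 (percentile 0.69, below the random range) when probes placed away from their gene were left out. Later mesoderm had 5 of 14 (percentile 3.04). Germ cell markers had 2 of 12 (percentile 0.105). The synaptonemal complex gene Sycp1 was detected in clone 1 only, at least 5.26-fold higher, beside 1 neighbouring spot that differed the same way. Neural markers had 9 of 14 (percentile 58.0). Sox1 was detected (-2.15 and -2.48, with a second probe in the opposite direction at 0.15), and Pax6 was not. Genes of the 2-cell stage had 3 of 9 (percentile 5.23). With the positive and significant flag definitive endoderm had 7 of 10 (percentile 22.4), inside the range of random lists, and germ cell markers 6 of 12 (percentile 1.15). With that flag primitive streak had 10, extraembryonic endoderm 8, trophoblast 7, mesoderm 10 and the 2-cell stage 6.

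Genes of signalling pathways that act on EpiSC were widely detected. All 14 Activin/Nodal receptors, effectors and regulators were detected on both arrays (percentile 99.95), as were 14 of 15 FGF receptors and FGF/ERK target genes (percentile 99.6). BMP targets and antagonists had 11 of 12 (percentile 98.6), and WNT targets had 8 of 12 (percentile 64.5). With the positive and significant flag the counts of Activin/Nodal, FGF/ERK and BMP genes were the same, at percentiles 97.8, 89.97 and 83.0. Their random ranges then reached the full lists, so no count could lie above them. Axin2, a common WNT feedback gene, was not well above background in either clone. Rnf43, a WNT feedback ligase, was 2.07-fold higher in clone 2. Fgfr4 was 4.71-fold higher in clone 1 by its brighter probe, but its other probe gave 1.14 log2 in the opposite direction, the mean of both was -0.55, and the brighter probe had a 2-fold neighbour.

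Genes of other cell types were present in both clones as well. Whether the cells were grown on feeder cells is not given in the sources used here. All 15 measured fibroblast genes were detected on both arrays (percentile 99.98), among them Col1a2 (4.88 in clone 1 and 5.01 in clone 2), Dcn (3.79 and 3.62) and Tagln (4.32 and 4.62). These 3 encode a collagen chain, a matrix proteoglycan and an actin-binding protein. Col1a1 gave no value. With the positive and significant flag the fibroblast count was also 15 (percentile 98.3). The random range of 9 to 15 then reached the full list, so no count could lie above it. Of 18 Hox genes, which pattern the body axis, 10 were detected on both arrays (percentile 30.7), including Hoxc6 (0.11 and 0.34). Blood and immune genes had 8 of 11 on both arrays (percentile 77.2), including the macrophage genes Csf1r (-0.35 and 0.48) and Lyz2 (0.44 and 0.20). Cd3e, a T cell receptor component, was 5.46-fold higher in clone 2 at a spot with a 2-fold neighbour. Of 7 Y-linked genes, 2 were detected on both arrays of these cells labelled female (percentile 4.99, with a median of 4 in random lists). These were Ddx3y (-2.81 and -3.18) and Sry (-3.99 and -3.96), and Eif2s3y and Zfy1 were detected in clone 1 only. Sry lay close to the lowest signal of detected probes (-4.54 and -4.55). With the positive and significant flag 5 of the 7 Y-linked genes were detected on both arrays (percentile 28.6). The fibroblast list differed little between clones, with a median of 0.12 log2 (clone 2 minus clone 1), inside the range of -0.07 to 0.23 of matched random lists.

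The remaining lists were mostly detected in full. On both arrays these were all 12 housekeeping, 12 epithelial, 12 mesenchymal, 16 glycolysis, 18 cholesterol synthesis, 14 p53 target, 12 unfolded protein response and 10 DNA methylation genes. Proliferation genes had 17 of 18, heat shock genes 8 of 9, interferon-stimulated genes 12 of 14, imprinted genes 21 of 27 and X inactivation RNAs 4 of 5.

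**Figure D1:**
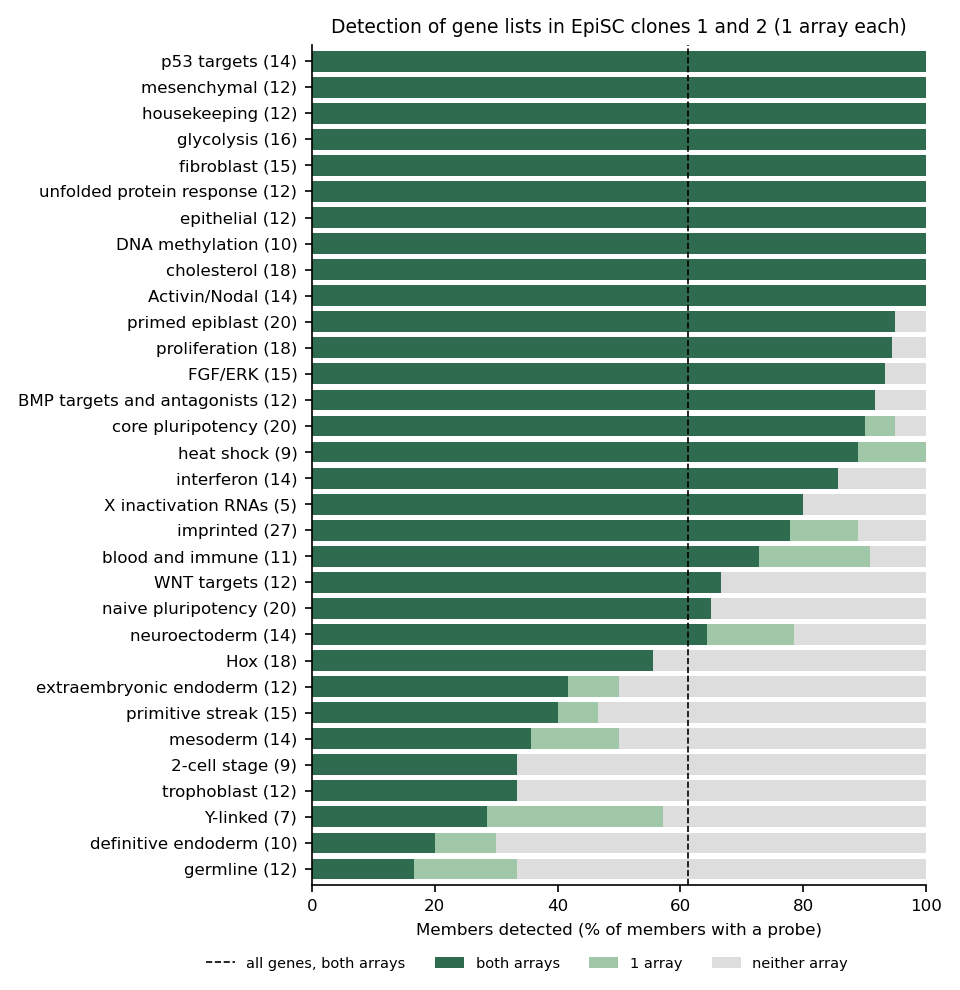
Share of the measured members of each gene list (number in brackets) that was detected on both arrays, on 1 array or on neither, in percent. The dashed line is the share of all genes detected on both arrays (61.3%), and core pluripotency and primed epiblast genes lie above it while the endoderm, trophoblast, mesoderm and germline lists lie below.

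Between the clones, 211 genes were at least 2-fold higher in clone 2 and 145 at least 2-fold higher in clone 1, which together are 2.56% of the measured genes. With normexp background correction the counts were 143 and 61. Of 29 lists with 3 or more measured members, 9 had a median outside the middle 95% of matched random lists.

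Epithelial genes formed the group that differed most. All 12 were higher in clone 2, with a median difference of 1.15 log2 against a range of -0.09 to 0.24 in random lists, and 8 were at least 2-fold higher. Cldn7 was 3.56-fold, Ocln 2.49-fold and Tjp3 2.19-fold higher. These belong to tight junctions, whose probes lie on chromosomes 11, 13 and 10. Crb3, an apical polarity protein, was 2.92-fold higher. The keratins Krt8 and Krt18 of simple epithelia were 2.46-fold and 2.26-fold higher, the epithelial transcription factor Grhl2 2.59-fold, and the splicing regulator Esrp1 2.16-fold. The second probes of Krt8 (0.54 log2), Esrp1 (0.73) and Crb3 (0.95) were higher in clone 2 too, by less than 2-fold. E-cadherin (Cdh1) was 1.92-fold higher, and Epcam had a difference of 0.13 log2. Outside the list, another keratin of simple epithelia, Krt19, was 22.6-fold higher in clone 1. Evpl, an envelope protein of stratified epithelia, was 8.12-fold higher in clone 1. The Evpl spot had 2-fold neighbours in the same direction, and that of Krt19 had none in that direction. Of the spots behind the 12 genes, that of Cdh1 had a 2-fold neighbour in the same direction. Mesenchymal genes had a median of 0.12 and a mean of -0.04, inside the random range. Among them Zeb1, a repressor of E-cadherin, was 1.89-fold and N-cadherin (Cdh2) 1.53-fold higher in clone 1.

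Targets of p53 were higher in clone 2, 13 of 14, with a median of 0.43 log2 (random range -0.03 to 0.25). None reached 2-fold. Gtse1 was 1.88-fold and Btg2 1.68-fold higher, and the cell cycle inhibitor Cdkn1a 1.42-fold. Ccng1 had a difference of -0.08.

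Interferon-stimulated genes were lower in clone 2, 11 of the 12 measured, with a median of -0.57 log2 (random range -0.13 to 0.23). The antiviral membrane protein Bst2 was 3.08-fold higher in clone 1, and Isg15 1.58-fold, and Usp18 differed by -0.97 log2. Ddx58 had a difference of 0.22. Mx1 was not well above background in either clone. With normexp background correction the median was -0.30.

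Medians outside the random range were found in 6 further lists. BMP targets and antagonists were higher in clone 2 by a median of 0.31 log2 (8 of 11 members), with Bmp7 1.95-fold higher and Id1, a direct BMP target, 1.58-fold. With normexp correction their median of 0.41 lay inside its random range of 0.04 to 0.43. Trophoblast genes had a median of 0.51 over 4 measured members, of which 3 were higher in clone 2, Tfap2c and Ascl2 by 1.56-fold and 1.59-fold. The other, Gcm1, was read by a probe placed on a chromosome other than that of the gene. Without such probes the median was 0.64 over 3 members, outside a random range of -0.43 to 0.47. Mesoderm genes had a median of -0.43 and a mean of -0.25 over 5 members, 3 of them higher in clone 1 and 2 in clone 2. The transcription factor Twist1 was 2.88-fold higher in clone 1, a difference of -1.53 that was -0.34 with normexp correction, where the list's median was -0.08. With the mean of all probes of a gene that median was -0.18, inside the random range of that setting. Cholesterol synthesis genes had a median of -0.10 (12 of 18 higher in clone 1), and -0.23 with the authors' deposited values or normexp correction. Unfolded protein response genes had a median of -0.15 (7 of 12 higher in clone 1), -0.25 without spots that had a 2-fold neighbour, and -0.14 with normexp correction, just inside the random range. Core pluripotency genes had a median of -0.05 and a mean of 0.05, just outside a random range of -0.03 to 0.23, and the median was -0.15 without spots that had a 2-fold neighbour. It lay inside the random range with quantile normalization (-0.10), normexp correction (-0.11) and the authors' deposited values (-0.10).

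The other 20 lists had medians inside the range of random lists, and no direction is read from them. With the mean of all probes of a gene, WNT (0.32) and Hox genes (0.23) lay above their ranges. By the probe of each gene with the highest mean signal, the medians were 0.19 for primed epiblast, 0.03 for naive and 0.19 for primitive streak genes. Medians were -0.10 for extraembryonic endoderm, -0.14 for neural, 0.18 for Hox and 0.02 for blood and immune genes. They were -0.02 for FGF/ERK, 0.18 for Activin/Nodal, 0.17 for WNT, 0.06 for imprinted, -0.14 for X inactivation, 0.14 for heat shock and 0.01 for 2-cell-stage genes. For glycolysis, proliferation, DNA methylation and housekeeping genes they were 0.21, 0.06, -0.04 and 0.10.

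**Figure D2:**
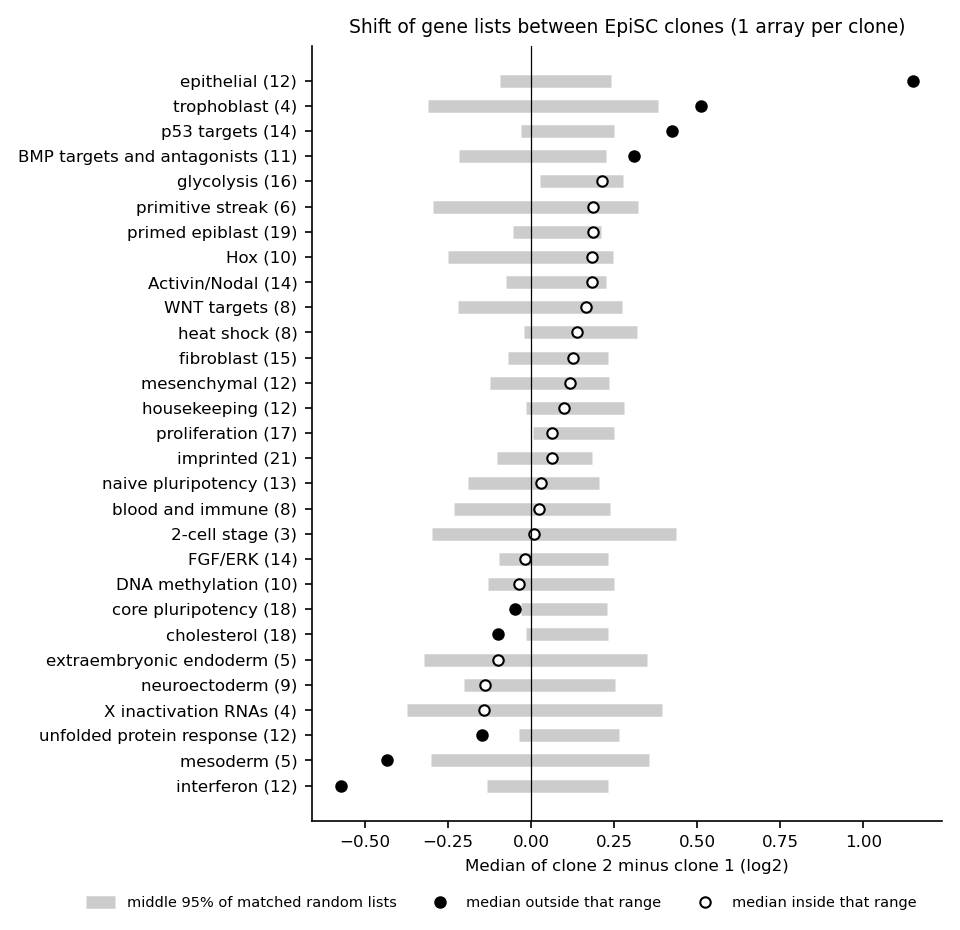
Median difference between clones (clone 2 minus clone 1, log2) of each gene list with 3 or more measured members (number in brackets), as a point, beside the middle 95% of matched random lists as a grey bar. Epithelial genes stand at 1.15 and interferon-stimulated genes at -0.57, and filled points mark the 9 lists outside their bar.

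**Figure D3:**
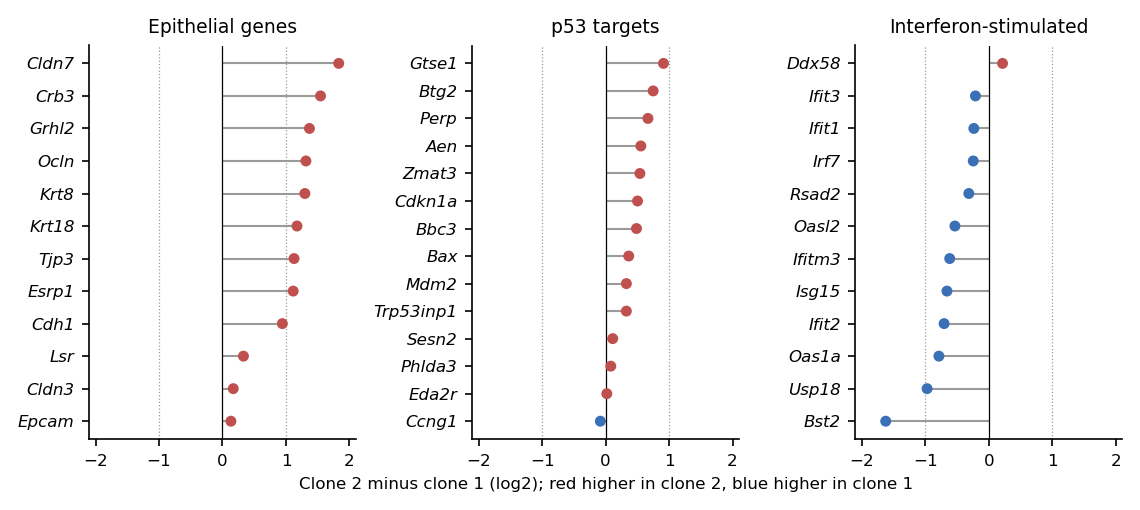
Difference between clones (clone 2 minus clone 1, log2) of each measured epithelial gene, p53 target and interferon-stimulated gene, with dotted lines at 2-fold. All 12 epithelial genes and 13 of 14 p53 targets lie above 0, and 11 of 12 interferon-stimulated genes lie below.

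Some imprinted genes, which are expressed from one parental allele, differed between clones although the list did not shift. Cdkn1c, a cell cycle inhibitor, was 3.91-fold and its neighbour Phlda2, a regulator of placental growth, 3.10-fold higher in clone 2. Their probes lie on chromosome 7 at 150644753 and 150687464 in mm9, and the Phlda2 spot had a 2-fold neighbour. The noncoding RNA Mirg of the Dlk1-Meg3 region on chromosome 12 was 3.68-fold higher in clone 2 (1.26 log2 by its second probe), and Meg3 of the same region was 1.39-fold higher. Mest was 8.23-fold higher in clone 1 by the 1 of its 3 probes that was measured on both arrays, at a spot with a 2-fold neighbour, and its difference of -3.04 was -1.54 with normexp correction. Slc38a4, an amino acid transporter, was detected in clone 1 only and was at least 8.43-fold higher there. H19 was measured at 5.15 and 5.26.

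Xist, the RNA that coats the inactive X chromosome, was detected in both clones, with 0.33 in clone 1 and -0.29 in clone 2. It was 1.53-fold higher in clone 1, and its second probe differed by -1.08 log2. Tsix was not well above background. Medians of chromosomes lay between -0.06 (X) and 0.05 (chromosome 11) log2 around the median of all genes, and 10 of 20 chromosomes lay outside the range of random lists (4 with normexp correction). The median of the 495 measured X-linked genes was -0.01.

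The single genes that differed most included genes from no common list. In clone 1 these were Krt19, Matn1 (21.1-fold), Acot1 (14.7-fold), Xrcc5 (13.2-fold), Serpina1a (11.8-fold), Serpina1c (10.1-fold), Tuba1c (9.50-fold), Aass (8.64-fold), Fam183b (8.28-fold), Mest, Evpl and Efcc1 (8.07-fold). Tuba1c, an alpha-tubulin on chromosome 15, was lower in clone 2 by both of its probes (-3.25 and -2.92). The second probe of Serpina1a differed by -0.28. In clone 2 these were Grin2a (9.57-fold), Rint1 (9.42-fold), Ino80b (6.99-fold), H2bc21 (6.38-fold), H2-Q1 (6.24-fold), Loxl4 (6.07-fold), Cd1d2 (5.78-fold), Cd3e, Mapt (5.33-fold), Ugt1a10 (5.30-fold), Cxcl11 (4.83-fold) and Ap1m2 (4.82-fold). Second probes of Mapt (-0.03) and Cxcl11 (-0.14) did not show the difference. With normexp correction Krt19 differed by -2.80 and Matn1 by -2.62.

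Among genes detected in 1 clone only, 148 were at least 2-fold higher in clone 1 and 128 in clone 2. Large bounds in clone 1 were at least 19.4-fold for the Notch ligand Dll4, 17.7-fold for Vmn1r194, 14.6-fold for Plxnc1 and 14.5-fold for Phgr1. The largest in clone 2 were at least 16.4-fold for Lacc1, 13.8-fold for the transcription factor Sox5, 13.2-fold for Olfr3, 11.8-fold for Zfp819 and 10.8-fold for Slc2a5. The 9 spots of these genes all had a 2-fold neighbour in the same direction.

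Large differences lay together on the arrays. Of the spots at least 2-fold apart and well above background on 1 or both arrays, 46.0% had another such spot in the same direction among their 6 nearest, against a median of 10.6% and a highest value of 13.7% in 1000 shuffles of the positions. For the 356 genes counted as at least 2-fold apart the share was 31.7%. Of the genes named for their difference, 7 of the 12 in clone 1 and 8 of the 12 in clone 2 had such a neighbour, as did 71.6% and 64.8% of the bounds of at least 2-fold. Without spots that had a 2-fold neighbour in either direction, 146 genes were at least 2-fold higher in clone 2 and 86 in clone 1. Of 65 genes at least 2-fold apart with 2 or more measured probes, 45 had all probes in the same direction and 16 had all of them at least 2-fold apart.

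**Figure D4:**
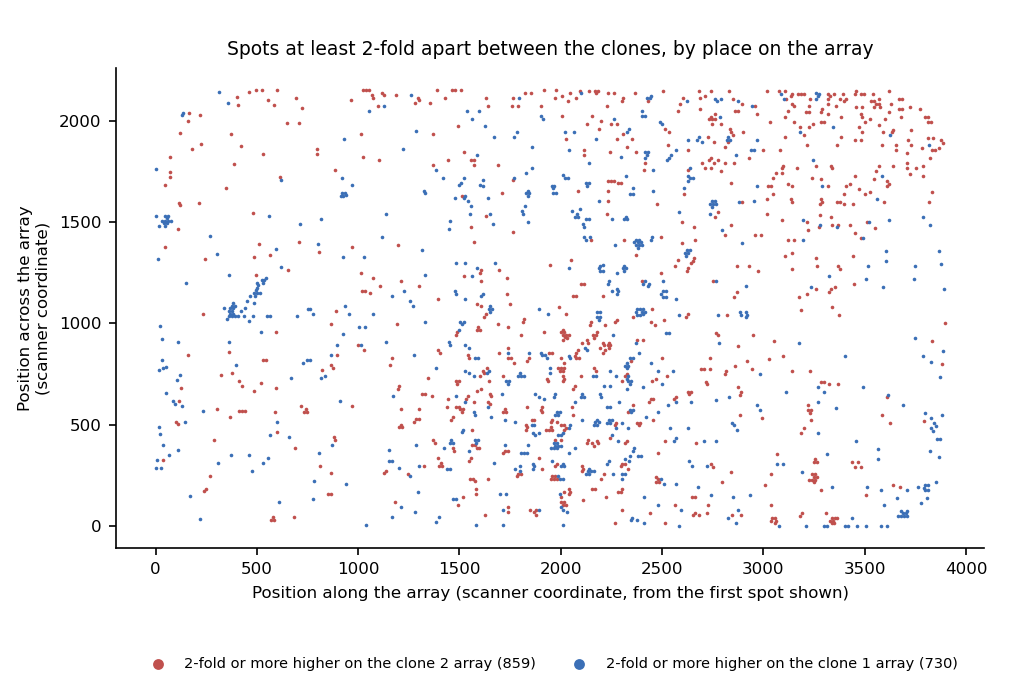
Places on the array of spots at least 2-fold apart between clones and well above background on 1 or both arrays (both axes in scanner coordinates), in red for 859 spots higher on the array of clone 2 and blue for 730 higher on that of clone 1. Spots of the same colour form patches and streaks, and 46.0% of them have a like neighbour.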

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

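The settings that leave out spots with a 2-fold neighbour, remove the trend with probe GC or leave out probes placed away from their gene were chosen after seeing the data. No paired analysis was possible because each clone has 1 array, and no array could be left out in turn. All 9 lists outside the random range kept their sign under each alternative that gave them a value, but not all stayed outside the range of random lists drawn in the same setting. Inside it were core pluripotency genes with quantile normalization, normexp correction and the deposited values, BMP and unfolded protein response genes with normexp correction, and mesoderm genes with the mean of all probes. No named gene at least 2-fold apart changed direction under the alternatives tested for single genes. The cause of the shifts that follow was not tested, except where fewer or more genes enter by construction. The offset of 50 in the normexp correction also shrinks the log2 differences of dim spots by construction, and its share was not separated. Genes at least 2-fold higher in clone 2 and clone 1 numbered 544 and 430 with the positive and significant flag, 839 and 631 with no filter on dim probes (both admit more genes), 802 and 462 at 1.5-fold, and 55 and 59 at 3-fold. With normexp correction 61 were higher in clone 1, and the share higher in clone 2 was 70.1% in place of 59.3%. Without spots that have a 2-fold neighbour, 86 were higher in clone 1. Genes detected in 1 clone only with a bound of at least 2-fold numbered 282 for clone 2 with that flag, and 42 for clone 1 and 45 for clone 2 without spots that have a 2-fold neighbour in the same direction. With normexp correction the list medians were 0.033 for primed epiblast, 0.58 for primitive streak and 0.43 for neural genes. These lay inside the random ranges of that setting (-0.13 to 0.14, 0.18 to 0.60 and 0.02 to 0.51). With that correction the list medians were -0.080 for mesoderm, 0.98 for epithelial, -0.23 for cholesterol and -0.30 for interferon genes. With the authors' deposited values they were -0.036 for heat shock, 0.0041 for glycolysis, -0.23 for cholesterol, -0.066 for proliferation and -0.067 for housekeeping genes. With quantile normalization they were 0.017 for glycolysis and -0.060 for housekeeping genes, and without spots that have a 2-fold neighbour 0.0079 for Activin/Nodal genes. Chromosomes outside the random range numbered 4 with normexp correction and 9 after the trend with probe GC was removed. The median spot SD was 0.13 log2 on both arrays with normexp correction. With the positive and significant flag the members detected on both arrays were 10 for primitive streak, 7 for definitive endoderm, 8 for extraembryonic endoderm, 7 for trophoblast, 10 for mesoderm, 6 for germline, 5 for Y-linked and 6 for 2-cell-stage genes. Against the negative controls they were the same numbers except 9 for mesoderm, and both rules call more genes in all (18815 and 19039 for the flag in clone 1 and clone 2). Which genes with weak signals count as detected therefore depends on the rule. Of 60 named genes, 33 moved by more than the 95% half-width of spot noise with normexp correction, 15 with the mean of all probes, 2 with the deposited values and 1 with quantile normalization. The list of 2-cell-stage genes had too few members without spots that have a 2-fold neighbour.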

Other observations

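Tests chosen only after the result was seen are those of the places of spots, of probes in the same direction, of epithelial genes without 2-fold neighbours, of random lists matched on probe GC and of the share of feeder cells. The second gene lists were chosen after the results of the first lists were seen, but before any value of their own members.

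Genes with several probes give differences that were read at separate places on the array. All measured probes of 11 genes were at least 2-fold higher in clone 2, and those of 5 genes in clone 1. The first group, chosen after its values were seen, held Eppk1 (2.59-fold), Espn (1.32 log2) and Marveld3 (2.36-fold), which encode an epithelial plakin, an actin-bundling protein and a tight junction protein. It also held Mirg, Cblc, Tmem184a, Padi2 (2.94-fold), Cyb5b (2.82-fold), Slc4a4 (2.63-fold), Cd164l2 and Akr1b10. The second group was Hltf (2.07-fold higher in clone 1), Ccdc85a (2.16-fold), Gria4 (3.27-fold), Gm9112 and Tuba1c. Among the genes with the largest differences and no 2-fold neighbour in either direction, also chosen after their values were seen, Ap1m2, Mal2 (4.42-fold) and Rab25 (3.88-fold) were higher in clone 2. In clone 1 they included Fam111a (7.64-fold) and the keratin Krt42 (4.94-fold). No enrichment was tested among these genes. Foxj1, a regulator of motile cilia, was 3.95-fold and Cyp1a1 4.17-fold higher in clone 2.

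Spots with large differences lay beside each other. Marks or uneven hybridisation on an array surface are a candidate cause, since 46.0% of spots at least 2-fold apart on 1 or both arrays had a like neighbour, above the highest of 1000 shuffles (13.7%), as did 31.7% of the counted 2-fold genes. A difference in RNA behind every such gene is argued against by the genes with several probes. In 69.2% of them (95% Wilson interval 57.2 to 79.1%) all probes went the same way, below the 90% set for the test after the result was seen. Probes of a gene can also read different transcripts, which was not tested, so the share of differences due to either stays open.

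The higher level of epithelial genes in clone 2 was weighed against several explanations. Without spots that have a 2-fold neighbour the median was 1.13 log2 over 11 genes, above the random range, and random lists matched on probe GC had medians up to 0.23 at the upper end of their middle 95%, which argues against array marks and GC as the whole cause. Fewer feeder cells in clone 2, if the cultures held any, would raise pluripotency genes as well, but the core list had a median of -0.047 (95% bootstrap interval -0.19 to 0.27), and fibroblast genes were not lower. In a second list of 24 epithelial genes not looked at before, the median was 0.54 over 19 measured genes (random range -0.08 to 0.19). Of these, 17 were higher in clone 2, with St14 2.65-fold, Lad1 2.79-fold and Dsp 2.43-fold higher. Krt19, Krt42 and Evpl, in neither list, were higher in clone 1. The Evpl spot had 2-fold neighbours in the same direction. The Krt19 spot had no 2-fold neighbour in the same direction, and that of Krt42 had none in either direction. A difference in part of an epithelial programme of the EpiSC, or a larger share of another epithelial cell type (untested), may therefore underlie the higher epithelial genes. With 1 array per clone, a difference between these cultures or RNA preparations cannot be told apart from one between the clones.

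The lower interferon-stimulated genes and higher p53 targets of clone 2 were followed in second lists of genes not looked at before. Over 24 measured interferon-stimulated genes the median was -0.25 log2 (random range -0.12 to 0.15). Of these, 15 were higher in clone 1, including Gbp3 (2.16-fold) and Herc6 (2.12-fold), and 9 in clone 2, including Psmb9 (0.55 log2). Over 14 p53 targets the median was 0.23 (random range -0.12 to 0.20), with 13 higher in clone 2, including Plk2 (1.80-fold) and Dcxr (1.63-fold). Without spots that have a 2-fold neighbour the first lists had medians of -0.62 and 0.49 (the latter over 11 genes, all higher in clone 2), both outside their ranges, and the second interferon list stayed outside at -0.25, while the second p53 list had 0.19, inside its range of -0.14 to 0.20. A weaker interferon response in clone 2 may thus extend beyond the first list, while the p53 shift held in the first list and its extension to further targets is less certain, and whether either belongs to the clone or to the culture stays open.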
